A study of Homo sapiens with 15 samples.

How the data were processed

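Exosomes were pelleted from serum, their total RNA was extracted with a column kit, and small RNA libraries were prepared with a ligation-based kit, size-selected on a gel, pooled and sequenced as single reads on an Illumina HiSeq instrument, per the labels' protocols. Each of the 15 libraries (5 healthy, 10 myeloma) is from another person, and groups were taken from the labels. The submitters' processing notes name CASAVA 1.8.2 and the genome build hg19. The aligner, the counting program, the miRNA database release and the treatment of reads that match several miRNAs are not given in the sources used here, so reads from near-identical miRNAs may have been counted for each or divided between them.

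Per the file headers, the authors' files give a read count for each pairing of a mature miRNA with a precursor hairpin, a total, and a normalized value. The 3 count columns held the same whole numbers in 15 of 15 files. The deposited normalized value is the count scaled by the column's sum (CPM), as checked on the values, and was not used. Each file has 2252 rows with 2042 mature names. Since 154 names stand in more than 1 row, 1 per precursor, and the repeated rows hold the same count for all but 35 of them, the highest value per mature name was kept. The column's sum was 119.1% to 137.2% of the total over mature names kept once. Library totals here are those of the latter. No 2 libraries of a group agreed within sampling noise (the smallest chi-square per degree of freedom within a group was 57.0).

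Genome positions, host genes and GC content were taken from a GENCODE annotation of GRCh38 (not the build named in the notes, from which no coordinates were used) by matching precursor names to gene symbols, which succeeded for 1573 of 1600 precursors. The hairpins of miR-486 were among those not matched. GC content is that of the 5' or 3' side of the hairpin to which the arm belongs, known for 98.8% of tested miRNAs.

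Counts were filtered with filterByExpr by group, scaled with TMM factors (0.456 to 1.52) and tested with edgeR 4.0.16 (glmQLFit, glmQLFTest; R 4.3.3), myeloma against healthy, without covariates, at a Benjamini-Hochberg adjusted p of 0.05. The 518 miRNAs tested held at least 99.9% of the counts of every library. CPM values are edgeR's with TMM factors. Errors of means are SD over libraries and errors of log2 fold changes are SE. For edgeR the SE was taken as the size of the log2 fold change over the square root of the F statistic. It is therefore approximate, most of all at low counts. For arm ratios it is limma's. The fold changes compare fitted mean counts, so 1 high library in a group weighs more in them than in means of log2 values. The median log2 fold change over all tested miRNAs was -0.17.

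miRNA lists (cell and tissue sources, families, clusters, p53 and hypoxia responses, miRNAs tied to myeloma, entries overlapping other small RNA) were written from general knowledge. Some miRNAs stand in several lists. The 24 lists with 3 or more measured members were tested on log2 CPM (prior count 2) with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated one, and fry), and, added after seeing the data, by an exact permutation test of the list mean. A list of placental miRNAs of chromosome 19 had fewer than 3 measured members. Ratios of 5p to 3p counts, with 0.5 added to each, were tested with limma for 110 hairpins with both arms past the filter. Measures with 1 value per library were tested by two-sided exact permutation over all 3003 splits. Detected miRNAs were also counted after thinning to 121860 counts (mean of 20 draws).

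Named miRNAs followed a rule. They are, among those past the threshold with a mean of at least 50 CPM, the 12 highest and 12 lowest by log2 fold change, then the 10 most abundant, up to 4 most abundant members of each list, and a fixed set of 13 miRNAs. List members that passed are named as well where a count was 5 or fewer, after their values were seen. The design, the lists, this rule and most alternatives were fixed before the data were examined.

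On simulated counts with the means and depths of these libraries (518 miRNAs, 200 of them changed, 10 runs), edgeR recovered 16.3% of 2-fold and 77.1% of 4-fold changes at 2.69% false calls, DESeq2 1.42.0 25% and 82.9% at 3.87%, and limma-voom 13.9% and 66.1% at 2.45%. The arm test recovered 36% of 4-fold changes at 6.19% false calls over 110 hairpins. The simulation drew both arms of a hairpin independently, so these rates need not hold for arms that vary together.

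Alternatives were DESeq2's size factors, upper-quartile factors or library totals in edgeR, DESeq2's Wald test, limma-voom with quality weights, no filter or a mean of 50 CPM, a block for the replicate number, log10 total or the red cell index as covariate, totals without miR-486-5p and miR-451a, repeated rows summed, other cut-offs for library and arm measures, and each library left out in turn. Fits without the 2 shallow libraries, and without these and healthy replicate 5, were added after seeing the data. Alternatives for files without counts did not apply. Exact tests used Python 3.11.15 with numpy 2.4.6 and were checked against scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.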

Results

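Small RNA was sequenced from exosomes, the small vesicles that cells release into body fluids, which were pelleted from the serum of 10 patients with multiple myeloma, a cancer of plasma cells, and 5 healthy adults. Each person gave 1 library, so the spread between libraries of a group includes the differences between people. The question posed by the labels was how exosomal microRNAs (miRNAs) of the patients differ from those of the healthy adults. The numbers in the sample titles place every healthy library before every myeloma one. Separate preparation of the groups therefore cannot be told apart from disease in any difference reported below. Healthy libraries held 1073794 to 5987103 miRNA counts, and myeloma libraries held 121860 to 11579562. Myeloma replicates 1 and 2 were far shallower than the rest, with 156374 and 121860 counts, and a count of 0 in them allows a level of up to 13.9 and 16.2 CPM (counts scaled to a common library total, 3 counts taken as the limit), against 0.246 to 2.56 CPM in the other libraries. Counts and intervals cover counting error only, since amplified reads are not independent molecules.

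The libraries of both groups were dominated by the same few miRNAs. By the mean over all 15 libraries miR-21-5p, found in most tissues, was the most abundant, at 116670 ± 29953 CPM (SD, n = 5) in healthy serum and 129770 ± 98164 CPM (SD, n = 10) in myeloma serum. In the healthy group the mean of miR-451a was higher, raised by replicate 5. miR-21-5p was followed by miR-451a and miR-486-5p, both characteristic of red cells, then by miR-148a-3p, let-7a-5p, let-7f-5p, miR-26a-5p, miR-92a-3p, the liver miRNA miR-122-5p and let-7i-5p. The 10 most abundant miRNAs of a library took 60.5% ± 4.74 (SD, n = 5) of healthy counts and 60.2% ± 3.80 (SD, n = 10) of myeloma counts. By exact permutation over all 3003 splits of the libraries (two-sided), this share did not differ between the groups (p = 0.90, adjusted p = 0.98 over 6 measures).

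The remaining library measures also differed by less than their spread. The mean log10 total was 6.43 ± 0.27 (SD, n = 5) in healthy and 6.42 ± 0.71 (SD, n = 10) in myeloma libraries (exact permutation p = 0.98, adjusted p = 0.98). At 10 counts or more, 436.6 ± 52.8 miRNAs were detected in healthy and 455 ± 146 in myeloma libraries (exact permutation p = 0.79, adjusted p = 0.98). After every library was thinned to the smallest total, these numbers were 180.8 ± 23.5 and 183.8 ± 10.1 (exact permutation p = 0.70, adjusted p = 0.98). The red cell index is the log2 ratio of miR-451a to miR-23a-3p and is used as a sign of haemolysis. It was 5.86 ± 2.53 in healthy and 5.88 ± 1.42 in myeloma libraries (exact permutation p = 0.98, adjusted p = 0.98). The healthy mean was raised by replicate 5, whose index was 9.95. With 1 library left out, the myeloma minus healthy difference ran from -0.67 (without healthy replicate 2) to 1.04 (without healthy replicate 5). It did not pass in any of these fits. The distance of a library to the median of its group was 0.92 ± 0.47 log2 CPM in healthy and 1.09 ± 0.41 in myeloma libraries (exact permutation p = 0.49, adjusted p = 0.98). It was largest in myeloma replicates 2 and 1 (1.89 and 1.73) and healthy replicate 5 (1.75). Each median includes the library itself, and distances were not taken anew for each split. In groups of unlike size this p is therefore only a rough test of a difference in spread. Healthy replicate 5 stood apart. miR-451a took 29.8% of its counts (95% exact binomial interval 29.7 to 29.8), against 2.98% to 5.93% in the other healthy libraries, and its mean Spearman rho with its own group was 0.83, against 0.91 in the other 4 healthy libraries.

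Among miRNAs past the threshold at a mean of 50 CPM or more, the largest rises in myeloma over healthy serum were in miR-193b-5p, miR-1246, miR-125a-3p and miR-10a-3p, and the largest falls in miR-30b-5p, miR-23b-3p, miR-654-5p and the lymphocyte-enriched miR-150-5p. miR-1246, whose sequence also lies within U2 small nuclear RNA, went from 38.1 ± 24.1 CPM (SD, n = 5) to 656.3 ± 659 CPM (SD, n = 10), a log2 fold change of 4.10 ± 0.73 (SE), and was above the healthy median in 10 of 10 patients. miR-193a-5p rose from 155 ± 123 to 1546 ± 658 CPM (log2 fold change 3.32 ± 0.60, SE) and miR-629-5p from 908 ± 391.98 to 4921 ± 1964 CPM (2.44 ± 0.41, SE), again in 10 of 10 patients. miR-30b-5p, of the miR-30 family, fell from 224 ± 278 to 36.6 ± 14.96 CPM (log2 fold change -2.60 ± 0.50, SE) and was below the healthy median in 10 of 10 patients. Among the most abundant miRNAs, miR-148a-3p rose from 28455 ± 9309 to 61406 ± 31501 CPM (log2 fold change 1.11 ± 0.39, SE, adjusted p = 0.037) and miR-26a-5p fell from 66578 ± 15961 to 35865 ± 6777 CPM (-0.89 ± 0.26, SE, adjusted p = 0.015). The log2 fold change of miR-148a-3p was 0.91 to 1.21 with 1 library left out at a time, and its call was lost in 7 of these 15 fits, those without healthy replicate 1, 2 or 4 or myeloma replicate 3, 4, 5 or 7 (adjusted p up to 0.10).

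By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 143 of 518 tested miRNAs passed an adjusted p of 0.05, of which 69 were higher and 74 lower in myeloma. Of these, 29 had no overlap between the groups, which chance gives for 0.0666% of miRNAs, and they included miR-1246, miR-629-5p, miR-193a-5p, miR-27a-5p, miR-30b-5p, miR-370, miR-199a-5p and miR-26a-5p. Without the 2 shallow libraries 71 were higher and 61 lower, and without these and healthy replicate 5 the counts were 93 and 67.

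**Figure D1:**
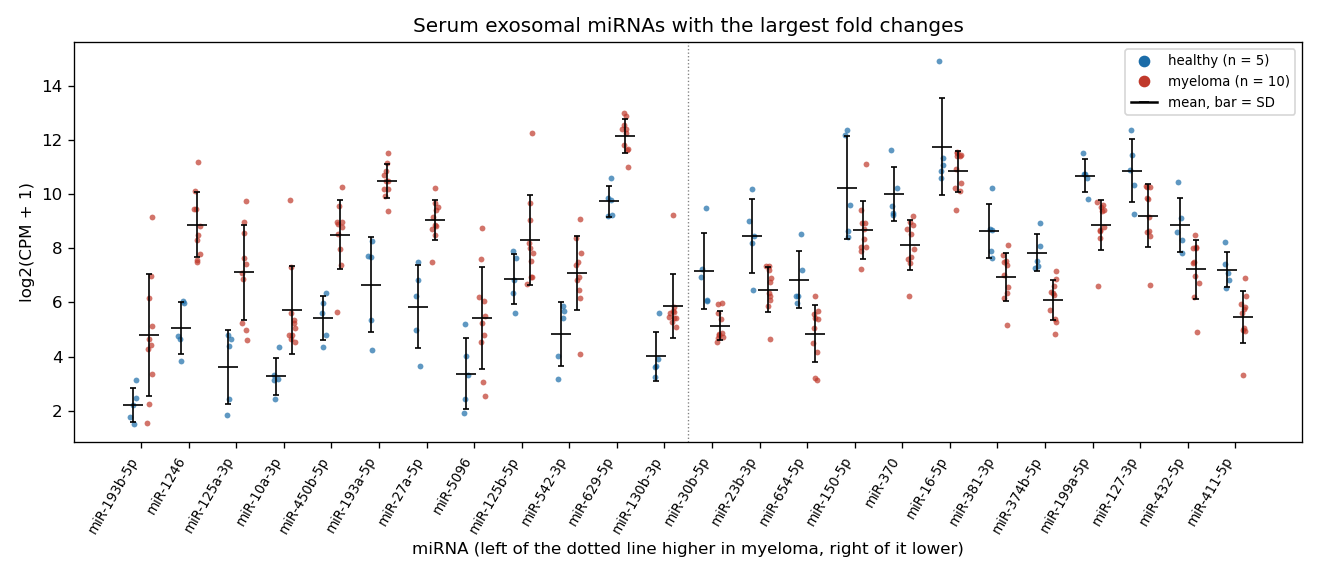
Levels of the 12 miRNAs with the largest rises and the 12 with the largest falls among those past the threshold and at a mean of 50 CPM or more, as log2(CPM + 1). Each point is a library (5 healthy, 10 myeloma), the short line is the mean and the bar the SD. All 10 myeloma libraries lie above all 5 healthy ones for miR-1246, miR-10a-3p, miR-193a-5p, miR-27a-5p and miR-629-5p, and the healthy mean of miR-16-5p is raised by 1 library.

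The 12 largest rises at 50 CPM or more included miR-125a-3p and miR-10a-3p, each the less abundant arm of its hairpin. miR-193b-5p went from 4.03 ± 2.30 to 87.4 ± 173 CPM (log2 fold change 4.49 ± 1.20, SE, adjusted p = 0.011 by edgeR), miR-125a-3p from 15.4 ± 11.1 to 244 ± 265 CPM (3.99 ± 0.90, adjusted p = 0.0052) and miR-10a-3p from 9.65 ± 5.64 to 129.7 ± 268 CPM (3.75 ± 1.01, adjusted p = 0.011). miR-27a-5p went from 82.1 ± 67.7 to 587 ± 285 CPM (2.83 ± 0.59, adjusted p = 0.0036). miR-450b-5p (log2 fold change 3.33 ± 0.63) and miR-542-3p (2.44 ± 0.66), neighbours on chromosome X, rose as well, as did miR-5096 (2.66 ± 0.94), miR-125b-5p (2.47 ± 0.91) and miR-130b-3p (2.43 ± 0.79). Myeloma replicate 6 carried much of several of these changes. Without it the log2 fold change was 2.92 for miR-193b-5p, 2.18 for miR-10a-3p and 1.32 for miR-130b-3p, all still past the threshold, and miR-125b-5p lost its call (1.0045, adjusted p = 0.19). Without myeloma replicate 3 the log2 fold change was 3.48 for miR-1246 and 3.39 for miR-125a-3p. miR-5096 was at 3.54 without healthy replicate 2 and lost its call without myeloma replicate 2 (1.91, adjusted p = 0.081), as it did without myeloma replicate 1, 4 or 7 or healthy replicate 1, 3, 4 or 5 (2.38 to 2.70, adjusted p up to 0.12). miR-125b-5p also lost its call without any 1 of the healthy libraries or myeloma replicate 2, 4, 7 or 10 (2.25 to 2.73, adjusted p up to 0.12), and miR-130b-3p without healthy replicate 1, 2, 3 or 4 (2.28 to 2.41, adjusted p up to 0.063).

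Of the 12 largest falls at a mean of 50 CPM or more, 6 were miRNAs of the 14q32 cluster. miR-370 went from 1265 ± 1081 to 323 ± 167 CPM (log2 fold change -1.97 ± 0.47, SE, adjusted p = 0.0064 by edgeR) and miR-127-3p from 2356 ± 1778 to 733 ± 426 CPM (-1.68 ± 0.51, adjusted p = 0.018). miR-654-5p (-2.08 ± 0.52), miR-381-3p (-1.79 ± 0.47), miR-432-5p (-1.66 ± 0.50) and miR-411-5p (-1.65 ± 0.45) completed this group, each below the healthy median in 10 of 10 patients. Outside it were miR-23b-3p (-2.26 ± 0.49), miR-150-5p (-2.05 ± 0.64), miR-374b-5p (-1.72 ± 0.41), miR-199a-5p (-1.71 ± 0.41) and miR-16-5p (-1.95 ± 0.59). miR-16-5p was at 7828 ± 12987 CPM in healthy and 2027 ± 873 CPM in myeloma serum, and its difference rested on healthy replicate 5, without which the log2 fold change was 0.03 (adjusted p = 0.97). Without the same library miR-30b-5p was at -1.41 (adjusted p = 0.0099), and without healthy replicate 4 miR-654-5p was at -1.48 and miR-370 at -1.36, both still past the threshold, whereas miR-381-3p (-1.17), miR-127-3p (-1.26) and miR-432-5p (-1.08) lost their calls. miR-150-5p lost its call without healthy replicate 4 (-1.53, adjusted p = 0.12) or 5 (-1.47, adjusted p = 0.089).

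The genes of miR-193a-5p, miR-1246, miR-629-5p, miR-30b-5p and miR-23b-3p lie on different chromosomes (GRCh38 coordinates of the GENCODE annotation). MIR193A lies on chromosome 17 at 31559996 to 31560083 between annotated genes, and MIR1246 on chromosome 2 at 176600980 to 176601052, also between genes. MIR629 lies on chromosome 15 at 70079372 to 70079468 in an intron of TLE3. MIR30B lies on chromosome 8 at 134800520 to 134800607 between genes, and MIR23B on chromosome 9 at 95085208 to 95085304 in an intron of C9orf3.

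miRNAs fixed for reporting before the data were examined, whatever their result, mostly did not pass. miR-451a was at 159480 ± 276030 CPM in healthy and 61337 ± 38372 CPM in myeloma serum (log2 fold change -1.38 ± 0.67, adjusted p = 0.14 by edgeR), miR-486-5p at 68598 ± 45568 and 91409 ± 41102 CPM (0.41 ± 0.39, adjusted p = 0.47), and miR-21-5p was at a log2 fold change of 0.15 ± 0.38 (adjusted p = 0.80). let-7b-5p was at -0.85 ± 0.40 (adjusted p = 0.13), miR-18a-5p at -0.96 ± 0.47 (adjusted p = 0.14), miR-15a-5p at 0.32 ± 0.64 (adjusted p = 0.76), miR-23a-3p at -0.51 ± 0.40 (adjusted p = 0.38), miR-122-5p at -0.07 ± 0.73 (adjusted p = 0.96) and the endothelial miR-126-3p at -0.77 ± 0.31 (adjusted p = 0.068). Without healthy replicate 5, miR-15a-5p passed at 2.23 (adjusted p = 0.0044). miR-451a then changed direction to 0.80 (adjusted p = 0.27), and the falls of let-7b-5p and miR-18a-5p shrank to -0.09 (adjusted p = 0.89) and -0.06 (adjusted p = 0.94). miR-126-3p passed without healthy replicate 1 or 3 or myeloma replicate 3, 4, 6, 8 or 10 (-0.95 to -0.74, adjusted p down to 0.019). The myeloid miR-223-3p passed, falling from 1872 ± 1177 to 669 ± 426 CPM (log2 fold change -1.48 ± 0.49, adjusted p = 0.028), but not without healthy replicate 2 (-1.20, adjusted p = 0.090) or 3 (-1.41, adjusted p = 0.051).

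Of the lists fixed before the data were examined, camera with a preset correlation called 1, the imprinted miRNA cluster at 14q32 (adjusted p = 2.6e-06). With an estimated correlation it did not pass (adjusted p = 0.90). Its miRNAs are transcribed from the maternal chromosome. Of its 41 measured members, 19 were lower in myeloma, none was higher and 22 did not pass by edgeR (23 lower adjusted over the list alone), and the median log2 fold change was -1.38. The tested members lie on chromosome 14 between 100869060 and 101066801 (GRCh38). The mean log2 CPM over the list was 5.98 ± 0.81 (SD, n = 5) in healthy and 4.70 ± 1.01 (SD, n = 10) in myeloma serum, a difference of -1.28 (exact permutation p = 0.023, adjusted p = 0.12 over 24 lists). The preset correlation between members was 0.01, and fry gave adjusted p = 0.17. Without healthy replicate 4, whose list mean of 7.17 was the highest, 8 members were lower, and without the 2 shallow libraries 17 were.

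The miR-30 family of 5 miRNAs had the most distinct list mean. miR-30b-5p and miR-30d-5p were lower in myeloma (log2 fold changes -2.60 ± 0.50 and -0.86 ± 0.27, SE), miR-30e-5p, miR-30c-5p and miR-30a-5p did not pass (-0.45, -0.47 and 0.30), and 2 were lower adjusted over the list alone. The list mean was 11.3 ± 0.22 log2 CPM (SD, n = 5) in healthy and 10.6 ± 0.23 (SD, n = 10) in myeloma serum (exact permutation p = 0.000666, the smallest that the 3003 splits can give, adjusted p = 0.016), and fry gave adjusted p = 0.0017. camera, which compares a list with the other miRNAs, gave adjusted p = 0.51 with the preset correlation and 0.90 with an estimated one. In the miR-23/27/24 clusters miR-23b-3p and miR-27b-3p (-1.04 ± 0.31) were lower, miR-24-3p was higher (1.26 ± 0.38), and 2 of the 5 did not pass, with the same counts adjusted over the list alone. Their list mean was 9.93 ± 0.33 in healthy and 9.29 ± 0.36 in myeloma serum (exact permutation p = 0.0033, adjusted p = 0.040), and neither camera (adjusted p = 0.61) nor fry (adjusted p = 0.12) passed. miR-24-3p lost its call without healthy replicate 1 (1.16, adjusted p = 0.053) and miR-27b-3p without healthy replicate 4 (-0.92, adjusted p = 0.056). Members of the miR-30 family differ by few bases, as do miR-23a-3p and miR-23b-3p, and miR-27a-3p and miR-27b-3p. Reads may have been divided within each of these sets in counting, so their single values are uncertain.

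**Figure D2:**
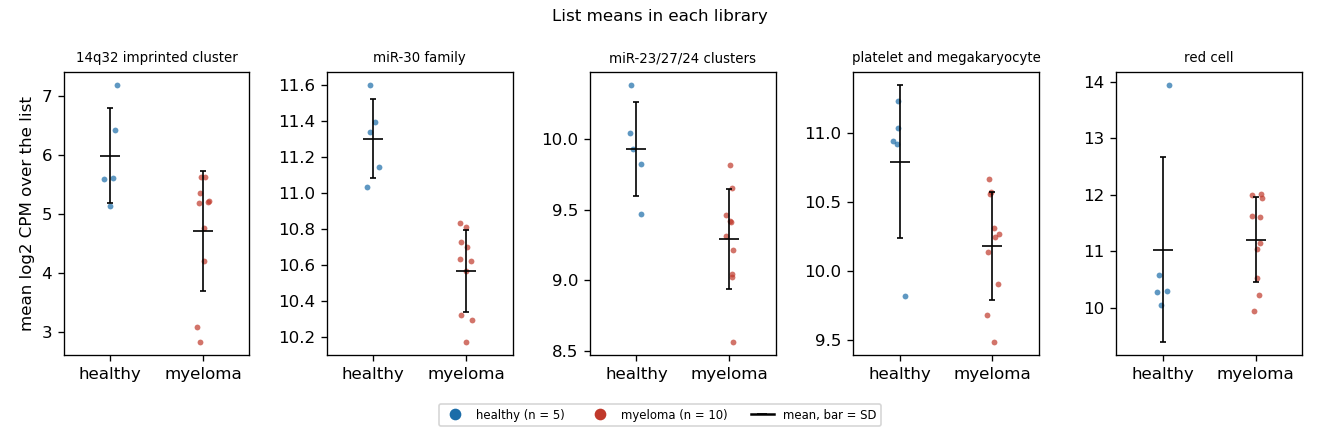
Mean log2 CPM over the members of 5 lists in each library, with the mean and SD of each group (5 healthy, 10 myeloma). All 10 myeloma libraries lie below all 5 healthy ones for the miR-30 family, the groups overlap for the 14q32 cluster, and 1 healthy library, replicate 5, is highest for the red cell list at 13.9 and lowest of its group for the platelet list at 9.82.

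Lists of blood cell miRNAs went in no single direction. Of 10 platelet and megakaryocyte miRNAs, miR-127-3p, miR-223-3p and miR-126-5p (-1.16 ± 0.34) were lower, miR-24-3p was higher and 6 did not pass (5 lower and 1 higher adjusted over the list alone), with list means of 10.8 ± 0.56 and 10.2 ± 0.39 (exact permutation p = 0.032, adjusted p = 0.13), and 3 of the 10 belong to the 14q32 cluster. Without healthy replicate 5 the difference of the platelet list means was -0.85 (exact permutation p = 0.001998, the smallest that these splits can give, not adjusted). Of 9 myeloid miRNAs, miR-146b-5p (-1.57 ± 0.41) and miR-223-3p were lower and 7 did not pass. Of 12 lymphoid miRNAs, miR-150-5p and miR-28-5p (-0.92 ± 0.33) were lower, miR-181b-5p was higher (1.497 ± 0.42) and 9 did not pass. Without healthy replicate 4 neither miR-150-5p (-1.53) nor miR-28-5p (-0.89, adjusted p = 0.071) passed. miR-150-5p was also lost without healthy replicate 5 (-1.47), and miR-28-5p without myeloma replicate 1, 5 or 11 (-0.91 to -0.86, adjusted p up to 0.064). Of 10 red cell miRNAs, miR-16-5p alone passed, and the median log2 fold change of -0.80 and the difference of list means of 0.18 had opposite signs (exact permutation p = 0.83). Without healthy replicate 5, 3 red cell members were higher and none lower. The difference of list means was then 0.91 (exact permutation p = 0.048, not adjusted). The counts of the myeloid, lymphoid and red cell lists were the same adjusted over the list alone, and none of these lists passed camera or fry.

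Of 23 measured miRNAs that have been tied to myeloma, miR-16-5p, miR-192-5p and miR-215 were lower, miR-181b-5p and miR-125b-5p were higher, and 18 did not pass (1 higher and 1 lower adjusted over the list alone). The list means were 10.1 ± 0.73 and 9.99 ± 0.41 (exact permutation p = 0.76), and without healthy replicate 5 miR-16-5p was at 0.03, miR-192-5p at -0.28 and miR-215 at -0.43, none past the threshold. miR-192-5p also lost its call without myeloma replicate 1, 4 or 10 (-1.31 to -1.22, adjusted p up to 0.057), and miR-215 without healthy replicate 3 or myeloma replicate 1, 2, 3, 4, 7, 8, 10 or 11 (-1.36 to -1.20, adjusted p up to 0.071).

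Further lists held a few changed members each. In the miR-99/100 and miR-125 families miR-99a-5p (1.94 ± 0.65) and miR-125b-5p rose and 3 did not pass (3 higher adjusted over the list alone). Of these, miR-100-5p passed without healthy replicate 5 (1.995) or myeloma replicate 8 (1.73). In the miR-320 family miR-320b (2.09 ± 0.64) and miR-320c (2.41 ± 0.68) rose and miR-320a was at 0.84 ± 0.40 (3 higher adjusted over the list alone). Without myeloma replicate 6 these values were 1.02 for miR-99a-5p, no longer past the threshold, 1.48 for miR-320b and 1.68 for miR-320c. miR-99a-5p also lost its call without healthy replicate 1, 2 or 4 (1.87 to 2.00, adjusted p up to 0.084), and miR-320b without healthy replicate 4 (2.05, adjusted p = 0.052). Of 11 endothelial and vascular smooth muscle miRNAs, miR-10b-5p (1.87 ± 0.64), miR-99a-5p, miR-145-3p (2.39 ± 0.62, 2.98 without healthy replicate 3) and miR-125b-5p rose, miR-126-5p fell and 6 did not pass (5 higher and 2 lower adjusted over the list alone), and fry's test for change in either direction gave adjusted p = 0.019. miR-10b-5p lost its call without healthy replicate 1, 2 or 4 or myeloma replicate 4, 6, 7 or 10 (1.37 to 1.97, adjusted p up to 0.10). Of 5 brain miRNAs miR-9-3p (3.35 ± 0.63) and miR-129-5p (2.15 ± 0.76) rose, from low levels of 2.27 ± 1.24 and 2.82 ± 2.13 CPM. miR-129-5p lost its call without healthy replicate 1, 2, 4 or 5 or myeloma replicate 4, 6 or 7 (1.34 to 2.34, lowest without myeloma replicate 6, adjusted p up to 0.13). Of 6 muscle and heart miRNAs miR-378a-3p (1.54 ± 0.39) and miR-499a-5p (2.35 ± 0.62, 1.76 without myeloma replicate 6) rose and miR-133a (-2.44 ± 0.57, -1.795 without healthy replicate 5) fell. Of 8 entries that overlap other small RNA, miR-1246 rose and miR-3653 (-2.79 ± 0.78) and miR-664a-3p (-2.31 ± 0.47) fell. miR-3653 lost its call without healthy replicate 4 (-2.08, adjusted p = 0.089), and it did not pass the filter in 2 of the 15 fits without 1 library. For the brain, muscle and small RNA lists the counts adjusted over the list alone were the same.

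In the other lists 1 to 3 members passed, or none did. miR-192-5p (-1.40 ± 0.47) and miR-215 (-1.36 ± 0.49) fell and miR-10b-5p rose among 10 kidney and gut miRNAs, the first pair alone passed among 6 p53-responsive miRNAs, and miR-192-5p fell and miR-148a-3p rose among 6 liver miRNAs. miR-146b-5p and miR-223-3p fell among 8 hypoxia and inflammation miRNAs, let-7e-5p (-1.37 ± 0.44) among 9 of the let-7 family, and miR-19b-3p (-1.37 ± 0.46) among 12 of the miR-17-92 cluster and its paralogs. let-7e-5p lost its call without healthy replicate 1 (-0.99, adjusted p = 0.11). miR-19b-3p lost it without healthy replicate 5 (-0.41, adjusted p = 0.45) or myeloma replicate 1 (-1.31, adjusted p = 0.053). miR-16-5p fell and miR-424-5p (2.37 ± 0.64) rose among 6 of the miR-15/16 family, and miR-181b-5p rose among 4 of the miR-181 family. No member passed among 8 epithelial miRNAs and 3 of the miR-29 family. miR-29c-3p passed without healthy replicate 5 (1.499, adjusted p = 0.023). Adjusted over the list alone these counts were the same, save that no member of the miR-17-92 list passed. Of the 24 lists, camera with the preset correlation called 1, camera with an estimated correlation none (1 with the preset one, 2 by exact permutation of list means), fry's directional test 1 and its test for either direction 1. Camera's direction differed in sign from the median log2 fold change for the endothelial, small RNA, hypoxia, liver, lymphoid, miR-29 and red cell lists.

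The balance between the arms of a hairpin, from whose 5' and 3' sides the 5p and 3p miRNAs are cut, changed in 24 of 110 hairpins with both arms measured, a comparison in which library scaling cancels. In miR-223, abundant in myeloid cells and platelets, the log2 ratio of 5p to 3p went from 0.18 ± 0.53 (SD, n = 5) to 2.85 ± 0.81 (SD, n = 10), as miR-223-3p fell. In miR-27a it went from -1.70 ± 1.82 to 2.38 ± 1.13, with miR-27a-5p higher and miR-27a-3p not past the threshold (log2 fold change -0.68). In miR-145 it went from -1.99 ± 1.58 to -5.69 ± 0.78, in miR-150 from 4.597 ± 0.85 to 2.17 ± 1.23, in miR-125a from 5.22 ± 0.84 to 2.19 ± 1.89, and in miR-21 from 10.7 ± 0.22 to 9.08 ± 0.63, as miR-21-3p rose (log2 fold change 1.70) and miR-21-5p was at 0.15. miR-145-5p was scarce, at a mean of 16.2 CPM in healthy and 8.2 CPM in myeloma libraries, with a count of 0 in 2 of the latter. With 5 instead of 0.5 added to each count, the change of miR-145 was -3.05 (adjusted p = 0.0023 by limma). Arms were paired by mature name, and some names stand for several hairpins (3 for miR-9-5p, 2 for miR-199a-5p). The log2 fold changes of miR-199a-3p and miR-199b-3p were nearly the same (0.4827 and 0.4831), so the same reads may have been counted for both. The ratio of miR-199a is therefore uncertain.

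By limma on the log2 ratios with Benjamini-Hochberg adjustment, the ratio rose in 9 hairpins and fell in 15. The changes were 2.68 ± 0.44 (SE, adjusted p = 0.00023) for miR-223, 4.08 ± 0.69 (adjusted p = 0.00030) for miR-27a, -3.70 ± 0.58 (adjusted p = 0.00017) for miR-145 and -1.60 ± 0.37 (adjusted p = 0.0041) for miR-21, each in 10 of 10 patients relative to the healthy median. In 15 of the 24 the arms were fitted in opposite directions, but in none did one arm pass as higher and the other as lower by edgeR, and in 1, miR-10b, both arms passed in the same direction. With both arms at a mean of 50 CPM or more, 42 hairpins remained and 11 passed, all 11 among the 24, and without the 2 shallow libraries and healthy replicate 5 the number was 37. With 1 library left out at a time, 18 of the 24 kept their call in every fit, and miR-10a, miR-148a, miR-199a, miR-338, miR-374b and miR-505 lost it in 1 to 10 of the fits. With 5 instead of 0.5 added to each count, 19 hairpins passed, 18 of them among the 24. miR-10b (-1.05, adjusted p = 0.15) and the same hairpins save miR-199a lost their calls.

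**Figure D3:**
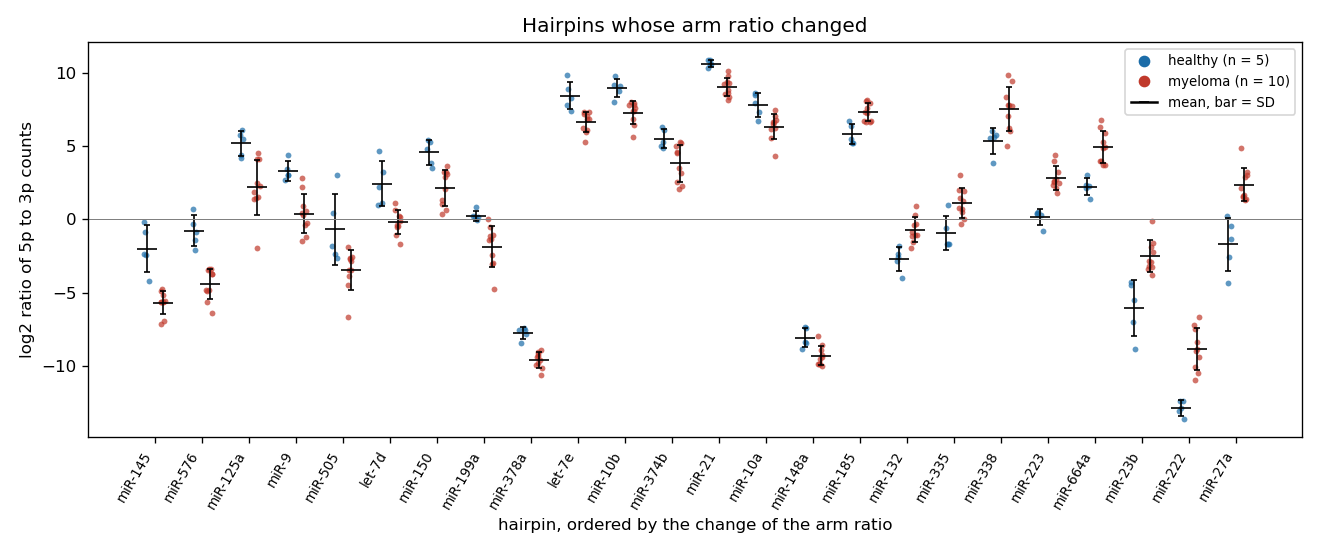
Log2 ratio of 5p to 3p counts (0.5 added to each) for the 24 hairpins whose ratio changed, in each library, with the mean and SD of each group (5 healthy, 10 myeloma). Hairpins are ordered by their change, from -3.70 for miR-145 to 4.08 for miR-27a. The 5p arm stays the more abundant one in both groups for miR-21 and the 3p arm in both for miR-378a.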

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

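The tests of platelet miRNAs and of miRNAs matched by GC content against the 14q32 cluster, of drift and separate preparation against the arm ratios, and of a few abundant miRNAs against healthy replicate 5 were chosen only after the result was seen, as were the fits without the libraries that stand apart. In each group, the gap of the highest or lowest library to its nearest neighbour was divided by the range of the group, and a value above Dixon's 95% critical value was taken as an outlier. Of 252 groups of values examined, 45 exceeded it, against about 13 expected by chance.

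In the healthy group all 24 outlying values belonged to replicate 5. It had the fewest miRNAs detected after thinning (139.8, against 185.7 to 197.2 in the others, gap over range 0.799) and the largest distance to the group median (1.75, against 0.65 to 0.84, ratio 0.822). Its list means were highest for the red cell list (ratio 0.864), the miR-17-92 cluster and paralogs (0.830), the miR-29 family (0.747) and the myeloma-associated list (0.793), and lowest for the platelet list (0.782). It was highest for let-7g-5p (0.859), let-7i-5p (0.785), miR-130b-3p (0.712), miR-15a-5p (0.787), miR-16-5p (0.833), miR-18a-5p (0.832), miR-20a-5p (0.793), miR-29b-3p (0.728), miR-29c-3p (0.780), miR-30e-5p (0.740), miR-363-3p (0.845), miR-451a (0.765) and miR-93-5p (0.719), and lowest for miR-10a-5p (0.813), miR-128 (0.721), miR-199a-3p (0.9) and miR-664a-5p (0.712).

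For this library a few miRNAs taking most of the counts do not account for the pattern, since the other miRNAs did not shift alike. Without its 10 most abundant miRNAs, the median size of its deviations about their own median was 1.41 log2 CPM over 217 miRNAs, 2.66 times the largest of the other healthy libraries (0.53). A larger share of red cell RNA is a candidate explanation, as 9 of the 10 red cell miRNAs were higher in it than in every other healthy library, by a mean of 3.64 log2 CPM over the 10, whereas the median deviation of miRNAs outside the list was 0.09. The trend of its deviations on GC content (Spearman rho -0.175 across miRNAs, which are not independent replicates) was too weak to account for the whole and too strong to be set aside. No biological explanation was tested, since the design names none for a single healthy adult, and without this library the log2 fold changes were 0.03 for miR-16-5p, -0.28 for miR-192-5p and -0.43 for miR-215, none past the threshold.

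Shallow libraries do not account for the lower levels of the 14q32 cluster in myeloma, as 17 members were lower without the 2 shallowest, nor does GC content, as miRNAs outside the cluster matched to its members within 2.5 GC points had a median log2 fold change of -0.0904 (bootstrap interval -0.20 to 0.06), against -1.38 in the cluster. Removal of a linear trend on GC content, planned first, decided nothing, since the trend was only -0.0020 per GC point. Less platelet RNA in the myeloma samples may contribute, since the median log2 fold change of 7 platelet miRNAs outside the cluster was -0.77, but its bootstrap interval of -1.16 to 0.48 is wide, and of the 3 most abundant members miR-126-3p (mean 13877 CPM) was at -0.77, miR-191-5p (11617 CPM) at -0.42 and miR-24-3p (12555 CPM) at 1.26. Chance is not excluded for the camera call with a preset correlation, since 87 of 100 splits of the libraries, the real one included, called at least as many lists (1 in the real split, up to 7 in the others). Splits with several times the real number of lists point to a structure of the samples that moves miRNAs of a list together, and a difference that goes with the disease stays open and was tested only by the group comparison. Separate preparation of the groups cannot be told apart from such a difference.

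Of 100 splits, only the real one gave as many as 24 hairpins whose arms changed apart (at most 16 in the others). Likewise only the real one gave as many as 143 miRNAs past the threshold (at most 15 in the others). Chance is thus an unlikely source of these totals, though only 100 of the 3003 splits were run. Single hairpins and miRNAs are not cleared of chance by this. GC content and shallow libraries do not account for the arm changes, since 24 hairpins passed after each library's trend on the GC difference of the arms was removed (22 of them the same), and 24 of the 24 kept at least 0.75 of their change without the 2 shallowest libraries. A steady drift over the order of the numbers in the sample titles is not borne out, as the arm score went against it within the myeloma libraries (Spearman rho -0.479, permutation p = 0.17). Separate preparation of the groups cannot be told apart from disease, here or in any other comparison of the groups. The numbering puts 0 myeloma libraries before any healthy one, and no value within a group can show a step between them. Both separate preparation and a difference in processing or sorting of arms in the disease stay open.

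In the myeloma group 21 values were outlying. Replicate 1 was lowest for the list of entries overlapping other small RNA (0.489), the miR-29 family (0.485), miR-1304-3p (0.576), miR-15b-5p (0.511), miR-29b-3p (0.800) and miR-9-3p (0.672), and replicate 2 for miR-181c-5p (0.572), miR-199a-3p (0.539) and miR-30e-5p (0.525). Both libraries are shallow. The 0 counts of replicate 1 for miR-1304-3p and miR-9-3p and of replicate 2 for miR-181c-5p allow levels above that of 1 or more other myeloma libraries, so depth alone can put these values apart. Replicate 3 was lowest for miR-125a-5p (0.484), miR-127-3p (0.497), miR-199a-5p (0.570) and miR-409-3p (0.566). Replicate 6 was highest for the epithelial list (0.690), the miR-99/100 and miR-125 families (0.593), miR-10a-3p (0.472), miR-130b-3p (0.820), miR-200a-3p (0.548), miR-21-5p (0.597), miR-499a-5p (0.478) and miR-99a-5p (0.483).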

How the results depend on the processing

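The fits without the libraries that stand apart, the exact tests of list means, the alternatives of scaling, filter, covariate and block for lists, the block for arm ratios, and leaving out each library for lists, arm ratios and thinned detection were chosen after seeing the data. Under the alternatives of scaling, test, covariate, summed rows, no filter and left-out libraries, the numbers of miRNAs higher and lower stayed within 1.5 times the values reported (47 to 80 higher and 56 to 80 lower with 1 library left out), and no called miRNA was called in the opposite direction. A mean of at least 50 CPM gave 35 higher and 40 lower, since only 228 miRNAs were then tested. DESeq2's size factors shifted the median log2 fold change of all miRNAs from -0.17 to -0.35, and voom and the fit without healthy replicate 5 to 0.03 and 0.13, and the fitted sign changed for 0 of the 143 miRNAs past the threshold under the 3 other scalings, for 1 with voom and for 2 without healthy replicate 5. Of 42 named miRNAs past the threshold, 25 kept their call with every library left out in turn and 24 in all other planned settings. DESeq2's Wald test gave no adjusted p for 3 of the 143, miR-16-5p among them. Library measures kept their side of the threshold in all settings run.

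As a check of pairing, the replicate number was used as a block. It gave 44 miRNAs higher and 47 lower, 42 and 37 of them shared, and 17 hairpins. Myeloma libraries whose number no healthy library bears do not inform the group difference in this fit. It rests on the 5 healthy libraries and the myeloma libraries of the same numbers, both shallow ones included. The lower counts therefore cannot be read as an effect of pairing. The numbers only name different persons. The deviations of same-numbered libraries correlated at -0.05 to 0.21, and none of the 5 healthy libraries correlated best with the myeloma library of its own number.

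Lists past the threshold numbered 0 with an estimated correlation and 2 by exact permutation of list means, against 1. Hairpins numbered 11 with both arms at 50 CPM or more, since only 42 were then tested, and 37 without the 3 libraries that stand apart, against 24. The cause of the last was not tested.

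miR-16-5p went from -1.95 to between -2.18 and 0.034 with 1 library left out, the latter without healthy replicate 5, and to 0.23 without the 3 libraries that stand apart. miR-29c-3p, at -0.08 and not past the threshold, was between -0.27 and 1.499 with 1 library left out (highest without healthy replicate 5), 1.09 with voom's quality weights and 1.54 without the 3 libraries. Without these 3, miR-15b-5p was at 1.26, miR-194-5p at 1.33 and miR-363-3p at 1.19, against -0.21, -0.13 and -0.77. Healthy replicate 5 was high in these miRNAs. Without it alone, miR-15b-5p was at 1.04, miR-194-5p at 1.13 and miR-363-3p at 1.02, so this library accounts for most of the shift in all 5. With voom the cause was not tested. Depth limits what the 2 shallow libraries can show, since a count of 0 there allows 13.9 and 16.2 CPM. Simulated 2-fold changes were recovered for 16.3% of miRNAs, a value that mixes depth with the spread between libraries and the group sizes.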

Other observations

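The tests in this part were chosen after the result was seen. Among 30 groups of neighbouring hairpins outside 14q32 (at most 10000 bases apart on 1 strand, with 3 or more measured miRNAs), 4 differed in their mean log2 CPM after adjustment over the 30. The MIR424 to MIR450B group on chromosome X (134540185 to 134546711, GRCh38) had 4 of 7 measured miRNAs higher in myeloma and none lower, miR-450b-5p, miR-424-5p, miR-542-3p and miR-450a-3p, and its mean was 4.84 ± 0.87 in healthy (SD, n = 5) and 6.57 ± 0.87 in myeloma libraries (SD, n = 10; exact permutation p = 0.0040, adjusted p = 0.045), above the healthy median in 9 of 10. miR-450a-3p lost its call without healthy replicate 4 (1.70, adjusted p = 0.071). The group of miR-188, miR-362, miR-500a, miR-501, miR-502, miR-532 and miR-660 on the same chromosome (50003148 to 50014683) had 4 of 8 higher and none lower. They were miR-188-5p (log2 fold change 3.02 ± 0.72, SE), miR-501-3p (2.26 ± 0.44), miR-502-3p (1.97 ± 0.47) and miR-500a-3p (1.58 ± 0.43), and the group mean was 5.33 ± 0.51 in healthy and 6.42 ± 0.51 in myeloma libraries (exact permutation p = 0.0047, adjusted p = 0.045), above the healthy median in 10 of 10. miR-500a, miR-501 and miR-502 are close in sequence, so their single values are uncertain.

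The group of miR-30b and miR-30d on chromosome 8 (134800520 to 134804945) was lower, at 7.12 ± 0.33 in healthy (SD, n = 5) and 6.24 ± 0.29 in myeloma libraries (SD, n = 10; exact permutation p = 0.000666, the smallest possible, adjusted p = 0.020), below the healthy median in 10 of 10. The group of miR-23a, miR-27a and miR-24-2 on chromosome 19 (13836287 to 13836659) was higher, at 7.59 ± 0.47 and 8.35 ± 0.42 (exact permutation p = 0.0060, adjusted p = 0.045), with miR-27a-5p and miR-24-3p past the threshold, whereas the fixed list of miR-23, miR-27 and miR-24, made of the 3p miRNAs of this group and of its paralog on chromosome 9, had a lower mean. miR-24-3p also has a hairpin on chromosome 9, so its counts cannot be assigned to this group. Without it the means were 6.58 ± 0.52 and 7.27 ± 0.43 (exact permutation p = 0.016, not adjusted), with 1 of 5 members past the threshold.

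Of all tested miRNAs, miR-3609, singled out after its values were seen, had the smallest p, at 15.5 ± 5.97 CPM in healthy (SD, n = 5) and 0.404 ± 0.566 CPM in myeloma serum (SD, n = 10), a log2 fold change of -4.89 ± 0.67 (SE, adjusted p = 0.00016 by edgeR). Its myeloma mean is near the limit of counting, so the size of this fold change is uncertain. In myeloma replicates 1 and 2 a count of 0 would allow 13.9 and 16.2 CPM. miR-151a-3p, an abundant miRNA that was singled out likewise and lies outside the rule for names, fell from 16472 ± 2439 to 5556 ± 1798 CPM (log2 fold change -1.57 ± 0.29, adjusted p = 0.0018), with no overlap between the groups.

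The less abundant arms did not rise as a class. Over 110 hairpins the mean log2 ratio of the less to the more abundant arm was -4.01 ± 0.08 in healthy (SD, n = 5) and -3.94 ± 0.16 in myeloma libraries (SD, n = 10; exact permutation p = 0.31), and the less abundant arm gained in 12 of the 24 hairpins whose ratio changed. Across miRNAs, which are not independent replicates, the log2 fold change was unrelated to the mean level (Spearman rho 0.03).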
